A study of Mus musculus with 9 samples.

How the data were processed

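Polyadenylated RNA from 9 whole-kidney samples of mice had been sequenced in 3 groups of 3 libraries: wild type (WT), deletion of Ybx1 from podocytes (ΔPod) and a Ybx1 mutant that podocytes cannot secrete (K2A). Per the labels' protocols, RNA was extracted with RNeasy columns, mRNA was purified on oligo-dT beads, and libraries were made with the ScriptSeq v2 kit, which marks the strand. The labels do not say that each library came from a separate animal, so the p-values measure the spread between samples. They give no sex, date or batch, and they name a supplier for wild-type animals only.

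The deposited values were whole-number counts per gene symbol in a pair of tables, each holding WT with 1 of the other groups. The submitters' processing notes list FastQC 0.11.9, MultiQC 1.10.1, Trim Galore 0.6.3, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2 1.30.0 and the build mm10, without the role or order of each tool. The strand setting of the counting and the handling of reads that match several places are not stated, so counts of near-identical copies, overlapping genes and antisense partners are uncertain. The tables held 52182 and 52169 symbols, of which 52163 were shared. For 3 shared symbols the WT counts differed between the tables, and these were left out, which left 52160. Of 19 symbols found only in the ΔPod table, 15 could be tested in a fit of its 6 libraries and 0 passed. The 6 symbols found only in the K2A table were not analysed here. Total counts ran from 30777142 to 46882253. Gene coordinates and transcript lengths were taken from GENCODE vM21 on mm10, where 17599 of the 18067 tested symbols (97.4%) had a unique match.

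Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. All 9 libraries entered a single fit with a group term, so that the 3 comparisons share an estimate of the spread. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and the edgeR quasi-likelihood test was used with Benjamini-Hochberg adjustment over the tested genes at a false discovery rate of 0.05. Values per library are CPM, counts scaled to a common library size after TMM, given as mean ± SD over 3 libraries, and fold changes are log2 values with their standard errors. A group without any count was set to a floor of 3 counts over the group, and folds against it are lower limits. Floors cover counting error only. An exact permutation test of a single value between groups of 3 cannot give a p below 0.1, so none was used for single genes. The median log2 fold change of all genes was 0.08 in ΔPod, 0.09 in K2A and -0.01 between the genotypes.

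The samples were grouped by the labels alone. The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule always named Ybx1, Nphs1, Wt1, Havcr1, Lcn2, Tlr4, Nlrp3, Casp1, Il1b, Il18, Adgre1 and Col1a1. For each genotype against WT it took the 10 higher and 10 lower genes with the largest fold change among called genes with a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes and pseudogenes. It also took the 10 shared calls with the largest fold change in the genotype that moved less, and up to 4 called members of each list. Where fewer than 5 genes passed, it took the 5 with the smallest p. Genes named outside this rule, such as Xist, Fos, Egr1, Cfd, Upk3a, Cyp4a14 and Idi1, were chosen after their values were seen. Some genes are not reported here.

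Of 44 gene lists fixed by symbol, 43 had at least 5 tested members. Adrenal gland markers, with 2 of 11 members tested, were left out. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Because both genotypes share the WT libraries, 20 simulated sets of unchanged groups against the same WT libraries (seed 1) gave the correlation, covariance and number of shared calls that shared controls alone produce. A further 20 sets, added after seeing the data, kept the length class of each library, with its effect and dispersion from a fit with the class as a term. Random lists for percentiles numbered 10000. They were matched on length and expression for the nephron segment and glomerulus lists, and on expression alone for X-linked genes that escape inactivation.

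The alternatives were other scaling factors (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom with sample weights, robust dispersion, no filter, a filter of 1 CPM in 3 libraries, only the 6 libraries compared, a replicate block, leaving out mitochondrially encoded genes, and leaving out each library in turn. Added after seeing the data were the slope of counts on transcript length as a covariate, the sign of that slope as a class term, fits on the libraries of a single class, and a pooled comparison of both genotypes with WT. The edgeR steps were tested on simulated counts with 200 changed genes per comparison. For ΔPod against WT they recovered 0% of 2-fold, 12% of 4-fold, 62% of 8-fold and 96% of 32-fold changes among 17780 genes with 2 false calls. For K2A against WT the shares were 0, 10, 42 and 88% among 17778 genes with 4 false calls, and for K2A against ΔPod they were 0, 4, 44 and 92% among 17731 genes with 1 false call.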

Results

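Gene counts were available for 9 kidney RNA libraries from mice on a C57Bl/6N background at 16 weeks of age. Polyadenylated RNA from whole kidney had been sequenced in 3 groups of 3 libraries each. The groups were wild type (WT), a deletion of Ybx1 from podocytes (ΔPod), and a Ybx1 mutant that podocytes cannot secrete (K2A). Ybx1 encodes the cold shock Y-box binding protein, which binds RNA and DNA and can be released from cells. Podocytes, the epithelial cells of the glomerular filter, make up a small part of the kidney, so the libraries mostly held RNA of tubule cells. WT 1, WT 2 and WT 3 held 37259488, 35565685 and 41237674 counts. ΔPod 1, ΔPod 2 and ΔPod 3 held 33169471, 38601434 and 46882253 counts, and K2A 1, K2A 2 and K2A 3 held 30777142, 33667551 and 39872389. At these depths 3 counts over a group correspond to 0.0269 CPM (counts scaled to a common library size) in WT, 0.0250 CPM in ΔPod and 0.0280 CPM in K2A, and a transcript with no count in a group was taken to lie below that level.

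Ybx1 (chromosome 4, 119277981 to 119294604 in mm10) was measured at 1190, 1585 and 1185 CPM in the WT libraries. It was measured at 1167, 881 and 605 CPM in the ΔPod libraries and at 1078, 1152 and 554 CPM in the K2A libraries. The group means were 1319.8 ± 229.6 CPM in WT, 884 ± 281 CPM in ΔPod and 928 ± 326 CPM in K2A (mean ± SD, n = 3 each). The log2 fold change of Ybx1 against WT was -0.58 in ΔPod (SE 0.38, adjusted p = 0.465) and -0.51 in K2A (SE 0.38, adjusted p = 0.725), and neither passed the edgeR test. All 6 mutant libraries lay below the lowest WT library. Ybx1 is transcribed in most kidney cells, so whole-kidney counts check the podocyte genotype only weakly, and pseudogene copies of Ybx1 could share its reads. With the slope of counts on transcript length as a covariate, chosen after seeing the data, Ybx1 passed in both comparisons at -0.96 in ΔPod and -0.84 in K2A, whereas with the sign of that slope as a term it did not (-0.86 and -0.81, adjusted p = 0.0806 and 0.0930). Over the alternatives its fold change ran from -0.96 to -0.36 in ΔPod and from -1.09 to -0.12 in K2A. The podocyte transcripts Nphs1 and Wt1, which encode nephrin and a transcription factor of the mature podocyte, did not pass in any comparison of the main fit.

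The libraries of every group were divided in the same way by transcript length. In WT 1, WT 3, ΔPod 3 and K2A 3 longer transcripts had the higher counts relative to the mean of all libraries, whereas in WT 2, ΔPod 1, ΔPod 2, K2A 1 and K2A 2 shorter transcripts did. This division ran along the first principal component, which held 71.5% of the variance. Genes for ribosomal proteins, which are short, took 0.975 to 1.14% of the counts in the first set of libraries and 2.39 to 7.77% in the other. Podocyte, proximal tubule, collecting duct principal cell and intercalated cell markers were higher in the first set within all 3 groups, beyond the range of length-matched random lists.

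**Figure D1:**
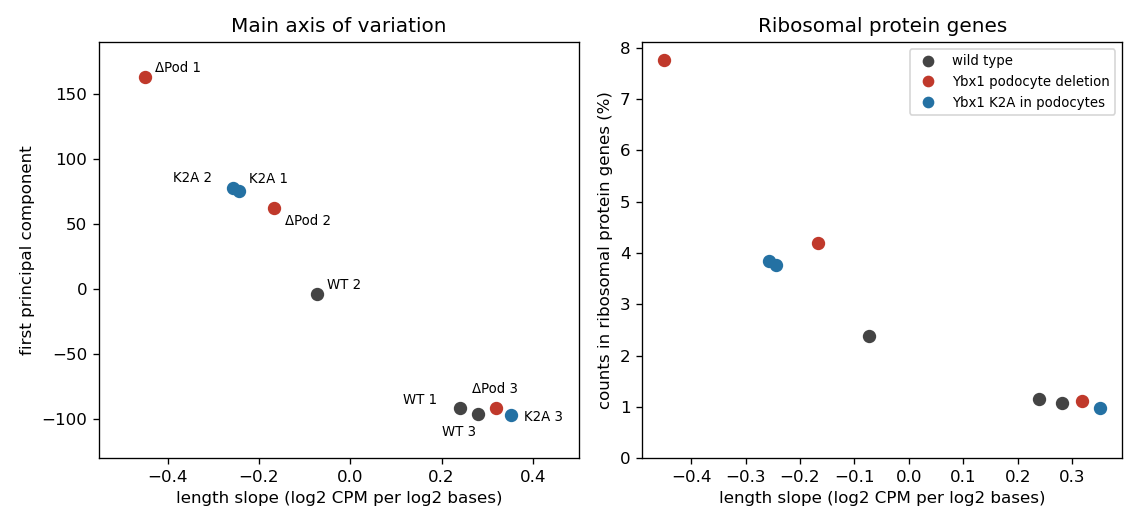
Length slope of each of the 9 libraries (slope of centred log2 CPM on log2 transcript length) against its score on the first principal component (left) and against the percentage of counts in ribosomal protein genes (right), with 1 point per library coloured by group. WT 1, WT 3, ΔPod 3 and K2A 3 have slopes above 0 and ribosomal protein shares of at most 1.14%.

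The comparison of ΔPod with WT was set up to address what the loss of Ybx1 from podocytes does to the transcripts of the whole kidney. Sex-linked transcripts also separated these groups (below), so an effect of genotype could not be told apart from a difference in sex. Transporter genes and a cytochrome P450 gene were among the genes with large differences. Of the genes in this paragraph and the next, Slc7a13, Cyp2j13 and Slco1a1 were on the fixed list of male-biased kidney genes. Slc7a12 was on the female-biased list. These lists held only 13 and 6 genes, so a gene outside them may still differ between the sexes. Slc7a13, an amino acid transporter of the late proximal tubule (chromosome 4, 19818725 to 19842218), fell from 1068 ± 63.6 CPM in WT to 3.06 ± 1.88 CPM in ΔPod (mean ± SD, n = 3; log2 fold change -8.45, SE 1.02, adjusted p = 0.0101). Cyp2j13, a P450 enzyme (chromosome 4, 96027534 to 96077546), fell from 423 ± 90.6 to 0.278 ± 0.0850 CPM (log2 fold change -10.54, SE 0.71, adjusted p = 0.00175). Slc7a12, another amino acid transporter (chromosome 3, 14480697 to 14505830), rose from 4.48 ± 1.84 to 226 ± 67.4 CPM (log2 fold change 5.65, SE 0.46, adjusted p = 0.00420). Slc17a2, of the sodium-phosphate transporter family (chromosome 13, 23806993 to 23825180), rose from 0.173 ± 0.0531 to 23.1 ± 9.32 CPM (log2 fold change 7.04, SE 0.52, adjusted p = 0.00243).

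Hdc, which makes histamine from histidine, rose by 8.32 on the log2 scale (adjusted p = 0.0136), and its ΔPod values had an SD of 84.0 CPM around a mean of 81.5 CPM. Cbr1, a carbonyl reductase, rose from 48.2 ± 11.9 to 844 ± 447 CPM (mean ± SD, n = 3; log2 fold change 4.13). Tmprss6, a membrane serine protease that restrains hepcidin, rose by 6.59, and Nup62cl, a nucleoporin-like gene on chromosome X, rose by 6.66. Igf2, an imprinted growth factor gene, rose by 5.27, and Galr2, a galanin receptor, rose by 4.42. The organic anion transporter genes Slc22a29 and Slc22a27 rose by 4.74 and 4.20. Among the genes that fell, Slco1a1, an organic anion transporter, went from 479 ± 90.9 to 0.106 ± 0.0338 CPM (log2 fold change -12.14, SE 1.83, adjusted p = 0.0225). Pzp, a protease inhibitor of the macroglobulin family, had a log2 fold change of -10.51, Mpped1 of -8.65 and Apoh, a plasma lipid-binding glycoprotein, of -7.69. Serpina1a and Serpina1b, which encode antitrypsins, had log2 fold changes of -4.50 and -3.58. Counts within the Slc22a, Serpina1, Cyp2j, Cyp4a and Gsta families, and of Igf2 and its antisense partner, could be shared between members or strands, so the single genes among them are uncertain.

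Transcripts known to differ between male and female mouse kidney moved with the groups. Of 13 tested male-biased kidney genes 11 fell and 2 were not called in ΔPod, with a median log2 fold change of -8.45 (also with genes at a count of 0 set to their bound). Adjusted over the list alone, 12 fell. This was the only list whose camera call held with an estimated correlation (adjusted p = 0.0166). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had a mean of 11.8 to 36.1 CPM in WT and no count in the 3 ΔPod libraries, which makes them at least 1443-, 1244-, 1042- and 472-fold lower. Of the 9 autosomal members 7 fell, with Cyp7b1, which hydroxylates oxysterols, at -6.71 (SE 0.41, adjusted p = 0.00151) and Acsm3, an acyl-CoA synthetase, at -7.55. Of 6 female-biased genes 2 rose, Slc7a12 and the prolactin receptor gene Prlr (log2 fold change 3.37), and 5 rose when adjusted over the list alone. Camera called this list up, with adjusted p = 0.361 with an estimated correlation. Xist, the X-inactivation transcript, had no count in the 3 WT libraries and 17.0, 18.8 and 124 CPM in the ΔPod libraries, at least 1982-fold higher as a group, with adjusted p = 0.0638. The labels give no sex for the animals, but by Xist and the Y-linked genes the WT libraries had a male and the ΔPod libraries a female pattern.

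Other groups held few called members in ΔPod. Of 25 tubular injury genes 1 rose, 1 fell and 23 were not called. Spp1, which encodes osteopontin, rose from 741 ± 51.1 to 2038 ± 165 CPM (mean ± SD, n = 3; log2 fold change 1.46, adjusted p = 0.0467), and Il34, a cytokine for macrophages (chromosome 8, 110741829 to 110805924), fell from 32.8 ± 6.77 to 6.23 ± 0.902 CPM (log2 fold change -2.39, SE 0.29, adjusted p = 0.00954). Adjusted over the list alone, 2 injury genes rose and 1 fell. Havcr1, which encodes KIM-1, had a log2 fold change of 0.58, and Lcn2, which encodes NGAL, of -0.69, and neither passed. Of 28 interferon response genes 1 rose, Gbp3, an interferon-induced GTPase, by 3.46 (adjusted over the list alone also 1). Of 16 NRF2 targets 1 rose, the glutathione transferase gene Gsta2 (1.96), and 1 fell, the malic enzyme gene Me1 (-1.52). Adjusted over the list alone, 2 rose and 2 fell. Camera called the NRF2 list down (adjusted p = 0.0322), with adjusted p = 0.896 with an estimated correlation and adjusted p = 0.0750 without ΔPod 3. Of 17 hypoxia genes 1 fell, Car9, a carbonic anhydrase, at -2.53 (adjusted over the list alone 2). Of 27 genes of fatty acid oxidation and PPARA targets 1 fell, Cyp4a12a, a fatty acid hydroxylase, at -6.88, whereas adjusted over the list alone 2 rose and 1 fell.

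Camera called 9 of 43 lists in ΔPod against WT, 3 up and 6 down. Immediate early genes were called up (adjusted p = 0.00561), with adjusted p = 0.896 with an estimated correlation and adjusted p = 0.619 without ΔPod 3. Atf3, a stress-induced transcription factor, was the only member to rise (2.20, adjusted p = 0.0319; adjusted over the list alone 2 rose), and in ΔPod 3 Fos reached 48.4 CPM and Egr1 165 CPM against at most 0.774 and 5.05 CPM in the other ΔPod and the WT libraries. Ribosomal protein genes were called up (adjusted p = 6.48e-07, with adjusted p = 0.952 with an estimated correlation), 80 of 81 had positive values and 0 were called. Their share of counts was 7.77% in ΔPod 1, 4.19% in ΔPod 2 and 1.11% in ΔPod 3, against 1.14, 2.39 and 1.07% in the WT libraries. Heat shock proteins (adjusted p = 0.000386), unfolded protein response (0.00962) and cholesterol biosynthesis (0.00486) were called down without a called member. Adjusted over the list alone, 1 unfolded protein response gene fell. With an estimated correlation these lists had adjusted p = 0.664, 0.882 and 0.361. Proximal tubule markers were called down (adjusted p = 0.0172, with adjusted p = 0.910 with an estimated correlation and adjusted p = 0.118 without ΔPod 1), with 1 of 25 members called, Slc7a13, which is also on the male-biased list. In ΔPod 3 the means of the proximal tubule and unfolded protein response lists lay within the range of the WT libraries. The liver and pancreas list, with Serpina1a and Serpina1b called of 6 tested members (3 adjusted over the list alone), was not called (adjusted p = 0.0625). Of 8 genes that vary between mouse substrains Wdfy1 fell (-3.12), and adjusted over the list alone 1 rose and 2 fell. Camera did not call that list (adjusted p = 0.284), and fry for changes in either direction gave adjusted p = 2.21e-05 (0.000460 in K2A).

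In all, edgeR called 178 of 18067 genes in ΔPod against WT, 72 higher and 106 lower, and 2495 genes had an unadjusted p below 0.05. All 178 showed no overlap between the 3 libraries of each group, as did 18.2% of all tested genes, where chance gives 10%. Of the called genes 4 lay on chromosome Y, 5 on X and 169 elsewhere. DESeq2 called 771 genes and a fit with the length slope as a covariate 2577, each with all 178 among them. The count depended on single libraries: it was 26, 34 and 23 without WT 1, WT 2 or WT 3, and 91, 36 and 411 without ΔPod 1, ΔPod 2 or ΔPod 3. Of the 36 genes named here that were called, 11 stayed called without any 1 library: Slc17a2, Slc7a12, Eif2s3y, Kdm5d, Cyp2j13, Pzp, Apoh, Wdfy1, Acsm3, Cyp7b1 and Serpina1a.

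**Figure D2:**
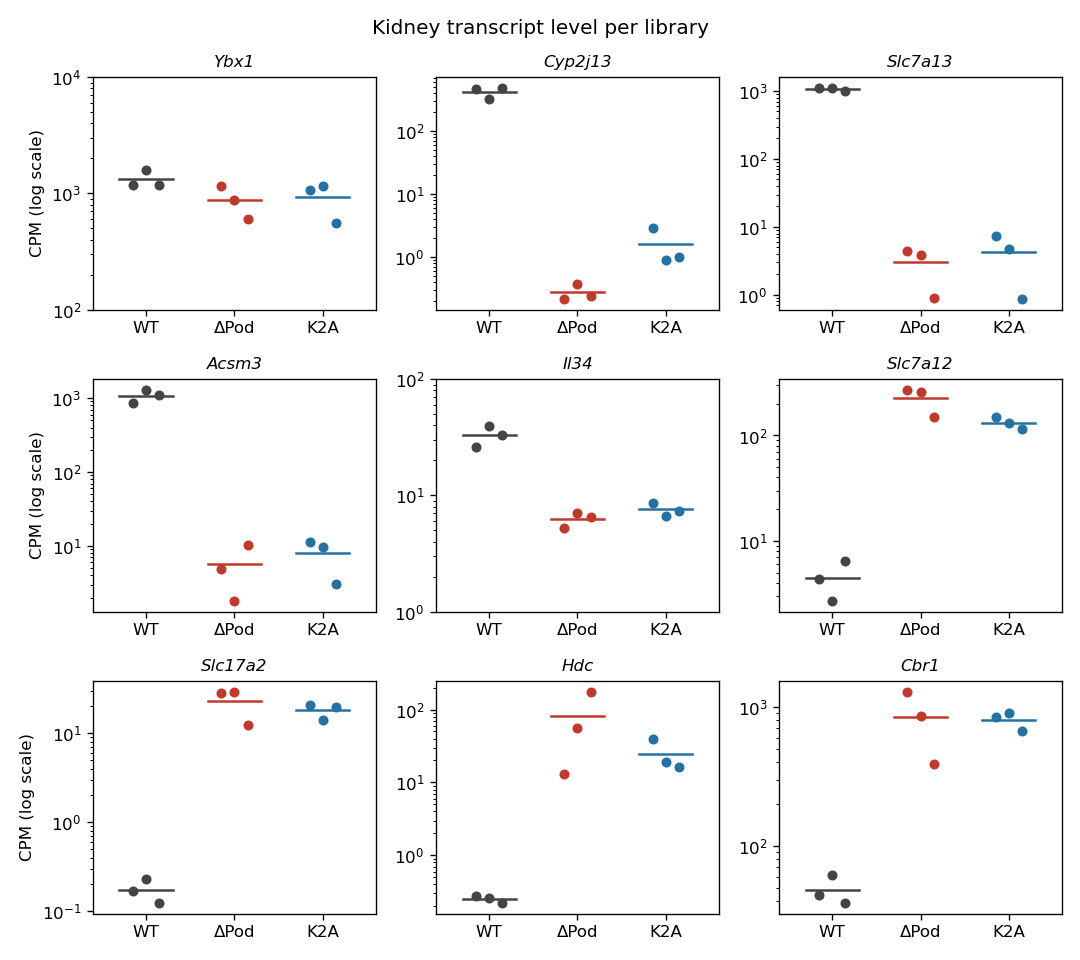
CPM per library on a log axis for Ybx1, Cyp2j13, Slc7a13, Acsm3, Il34, Slc7a12, Slc17a2, Hdc and Cbr1, with points for libraries and a line for the mean of each group (n = 3). For all of these genes, the 3 ΔPod and 3 K2A libraries lie on the same side of the 3 WT libraries with no overlap. Both comparisons with WT passed the edgeR test except for Ybx1, which passed in neither.

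The comparison of K2A with WT was set up to address what the loss of Ybx1 secretion from podocytes does to the kidney, with the protein still present. Sex-linked transcripts separated these groups as well, so genotype and sex could not be told apart here either. Of the genes below, Slc7a13 and Cyp2j13 were on the male-biased list and Slc7a12 on the female-biased list. Slc7a13 fell from 1068 ± 63.6 CPM in WT to 4.33 ± 3.30 CPM in K2A (mean ± SD, n = 3; log2 fold change -7.95, SE 1.0, adjusted p = 0.0151), and Cyp2j13 fell from 423 ± 90.6 to 1.60 ± 1.12 CPM (log2 fold change -8.05, SE 0.63, adjusted p = 0.00447). Slc7a12 rose from 4.48 ± 1.84 to 131 ± 17.1 CPM (log2 fold change 4.87, SE 0.44, adjusted p = 0.00836), and Slc17a2 rose from 0.173 ± 0.0531 to 18.2 ± 3.58 CPM (log2 fold change 6.70, SE 0.51, adjusted p = 0.00447). Cbr1 rose from 48.2 ± 11.9 to 807 ± 122 CPM (log2 fold change 4.06, SE 0.48, adjusted p = 0.0131).

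Further genes that rose in K2A were Tmprss6 (log2 fold change 7.70), Hdc (6.61), Nup62cl (6.35), Igf2 (5.74) and Galr2 (4.38). Arg2, the mitochondrial arginase, rose from 2.77 ± 0.486 to 66.4 ± 13.7 CPM (mean ± SD, n = 3; log2 fold change 4.58, SE 0.54, adjusted p = 0.0128), and it also rose in ΔPod (4.01, adjusted p = 0.0136). Fabp1, a fatty acid-binding protein, rose by 5.95 (SE 1.02, adjusted p = 0.0414), with a mean of 18.0 ± 20.3 CPM. Most of that mean came from K2A 3, as the values were 5.11, 7.44 and 41.3 CPM in K2A 1, K2A 2 and K2A 3. Pzp had a log2 fold change of -10.78, Apoh of -7.53 and Hrg, a plasma glycoprotein rich in histidine, of -7.37. Mpped1 fell from 7.81 ± 0.893 CPM to no count in K2A, which is at least 279-fold lower. Serpina1a and Serpina1b had log2 fold changes of -3.37 and -2.99.

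The transcripts that differ between the sexes moved in K2A as well. Of 13 male-biased genes 9 fell and 4 were not called, with a median log2 fold change of -7.53, and adjusted over the list alone 12 fell. The camera call held with an estimated correlation (adjusted p = 0.0111). Of the 9 autosomal members 5 fell, among them Cyp7b1 (-5.76, SE 0.39, adjusted p = 0.00369) and Acsm3 (-7.06, SE 0.85, adjusted p = 0.0131). Slco1a1 was at -7.90 and did not pass (adjusted p = 0.0597). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had log2 fold changes of -8.34, -9.55, -7.53 and -9.85. Their counts summed to 22 in K2A 1, 8 in K2A 2 and 0 in K2A 3, against 3404 to 4148 in the WT libraries. Xist was at 30.9, 30.6 and 331 CPM in the K2A libraries (adjusted p = 0.0547). Of 6 female-biased genes 2 rose, Slc7a12 and Prlr (3.03, adjusted p = 0.0495), and 5 rose when adjusted over the list alone. Camera called that list up, with adjusted p = 0.156 with an estimated correlation.

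Other groups in K2A again had few called members. Of 25 tubular injury genes 1 fell, Il34, from 32.8 ± 6.77 to 7.56 ± 1.02 CPM (mean ± SD, n = 3; log2 fold change -2.12, SE 0.28, adjusted p = 0.0173). Adjusted over the list alone, 2 rose and 1 fell. Camera called the injury list up (adjusted p = 0.0242), with adjusted p = 0.658 with an estimated correlation and adjusted p = 0.0675 without WT 2. The mean of its centred log2 CPM was 0.417 and 0.406 in K2A 1 and K2A 2, the K2A libraries with high adipocyte and urothelium markers, and -0.161 in K2A 3, against -0.303 to -0.0989 in the WT libraries. Spp1 was at 1293 ± 230.1 CPM with a log2 fold change of 0.80 that did not pass (adjusted p = 0.265). Havcr1 was at 0.11 and Lcn2 at 0.86, and neither passed. Of 16 NRF2 targets Gsta2 rose (1.98) and Me1 fell (-1.45), and adjusted over the list alone 2 rose and 1 fell. Gbp3 was the only 1 of 28 interferon response genes to rise (2.96; adjusted over the list alone also 1). Of 27 genes of fatty acid oxidation and PPARA targets Fabp1 rose and Cyp4a12a fell (-6.16), and adjusted over the list alone 3 rose and 1 fell. Of 19 clock genes Npas2, a clock transcription factor, fell (-3.45, SE 0.50, adjusted p = 0.0202; adjusted over the list alone also 1).

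Camera called 13 of 43 lists in K2A against WT, 6 up and 7 down, and male-biased genes alone held with an estimated correlation. Cholesterol biosynthesis was called down (adjusted p = 1.31e-06, with adjusted p = 0.0799 with an estimated correlation). None of its 23 members was called, 3 fell when adjusted over the list alone, and 19 had negative values, such as Idi1 (-2.60, adjusted p = 0.0547), which makes the isoprenoid precursor dimethylallyl diphosphate. Proximal tubule markers (adjusted p = 0.00204), heat shock proteins (0.0301), unfolded protein response (0.0471) and the renin-angiotensin list (0.0242) were called down. With an estimated correlation these had adjusted p = 0.837, 0.872, 0.887 and 0.819. Adjusted over the list alone, 2 unfolded protein response genes and 1 renin-angiotensin gene fell. In K2A 3 the means of the proximal tubule, heat shock and renin-angiotensin lists lay within the range of the WT libraries. The heat shock call was lost without WT 3 (adjusted p = 0.217) or K2A 1 (0.102), and the unfolded protein response call without WT 2, WT 3, K2A 1 or K2A 3 (0.123, 0.0802, 0.0519 and 0.196). Immediate early genes were called up (adjusted p = 0.0242, with adjusted p = 0.887 with an estimated correlation), but not without WT 2 (0.126) or K2A 3 (0.337).

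Markers of tissue around the kidney parenchyma stood apart in some K2A libraries. Adipocyte markers were called up (adjusted p = 0.0242, with adjusted p = 0.887 with an estimated correlation), but not without WT 2 (0.0693) or K2A 2 (0.0985). Cfd, which encodes adipsin, was at 139, 361 and 0.121 CPM in K2A 1, K2A 2 and K2A 3, and at 82.2 CPM in ΔPod 1. Lpl, which encodes lipoprotein lipase and is also transcribed in tubules, fell from 889 ± 77.9 to 250.4 ± 56.3 CPM (mean ± SD, n = 3; log2 fold change -1.83, SE 0.29, adjusted p = 0.0291). It was the only adipocyte marker of 10 that was called, while adjusted over the list alone 7 rose and 1 fell. Urothelium markers were called up (adjusted p = 0.0276, with adjusted p = 0.896 with an estimated correlation), but not without WT 2 (0.126), K2A 1 (0.0786) or K2A 2 (0.0985). The uroplakin gene Upk3a was at 14.3, 19.9 and 1.06 CPM in the K2A libraries. Ribosomal protein genes were called up (adjusted p = 0.00350, with adjusted p = 0.907 with an estimated correlation), but not without WT 3 (0.0620), K2A 1 (0.130) or K2A 2 (0.259), and their share of counts was 3.77, 3.84 and 0.975% in the K2A libraries. With the length slope as a covariate the ribosomal list had a median of -0.04. The list of genes that vary between mouse substrains was called down (adjusted p = 0.0242, with adjusted p = 0.658 with an estimated correlation, and 0.0629 without K2A 1), and of its 8 members Entpd4, a Golgi nucleotidase gene, fell (-2.35, adjusted p = 0.0176), and adjusted over the list alone 1 rose and 2 fell.

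In all, edgeR called 153 of 18067 genes in K2A against WT, 58 higher and 95 lower, and 1919 genes had an unadjusted p below 0.05. All 153 showed no overlap between the 3 libraries of each group, as did 20.1% of all tested genes, where chance gives 10%. Of the called genes 4 lay on chromosome Y, 2 on X and 147 elsewhere. DESeq2 called 753 genes and a fit with the length slope as a covariate 2864, each with all 153 among them. The count was 3, 23 and 5 without WT 1, WT 2 or WT 3, and 13, 12 and 173 without K2A 1, K2A 2 or K2A 3. Of the 36 genes named here that were called, Cyp2j13, Apoh and Cyp7b1 stayed called without any 1 library.

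In 24 lists with 352 tested genes the main fit called no gene and camera made no call in either comparison with WT. Among them were podocyte, endothelial, mesangial, thick ascending limb, distal convoluted tubule and collecting duct markers, TLR4 and NF-kappaB signalling, the NLRP3 inflammasome, macrophages, fibrosis, oxidative phosphorylation and the cell cycle. Adjusted over each list alone, 5 genes rose and 1 fell in ΔPod, among them 1 of the TLR4 and NF-kappaB list and 1 intercalated cell marker that rose, and 3 rose and 1 fell in K2A, again with 1 intercalated cell marker that rose. With the length slope as a covariate camera called podocyte markers up in ΔPod (adjusted p = 0.00242) and, in K2A, oxidative phosphorylation down (0.000190) and TLR4 and NF-kappaB signalling (0.0336) and mitochondrially encoded genes (0.000988) up. With the class term these 3 lists were called the same way in K2A, as were corticosteroid targets and neuronal markers up, and the podocyte list in ΔPod was not called (0.214). Tlr4, the endotoxin receptor, was at 2.29 ± 0.423 CPM in WT, 3.99 ± 0.723 CPM in ΔPod and 3.84 ± 1.22 CPM in K2A (mean ± SD, n = 3 each; log2 fold changes 0.80 and 0.74, adjusted p = 0.356 and 0.498). The inflammasome genes Nlrp3 (log2 fold changes -0.67 and -0.41), Casp1 (0.91 and 0.93), Il18 (-0.18 and -0.52) and Il1b (2.03 and 1.01) did not pass in ΔPod or K2A. Adgre1, a macrophage marker, was at 0.30 and -0.20, and Col1a1, a fibrillar collagen gene, was at -1.37 and -2.10, again without passing. On simulated counts with the same spread, the edgeR test recovered 0% of 2-fold, 12% of 4-fold and 62% of 8-fold differences between ΔPod and WT, and 0, 10 and 42% between K2A and WT, so differences of such sizes in these genes were not detectable reliably. In ΔPod the podocyte, complement, mitochondrially encoded and urothelium lists had a positive median and a camera direction of down without a call. In K2A the mesangial, complement, clock and erythrocyte lists did so, and the YBX family list had a negative median and a direction of up.

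Both genotypes shared most of their called genes. The edgeR test called 124 genes the same way in both, 49 higher and 75 lower, and 0 in opposite directions. Of these 118 lay outside chromosomes X and Y. The 10 shared genes with the largest fold change in the genotype that moved less were Pzp, Kdm5d, Eif2s3y, Mpped1, Ddx3y, Cyp2j13, Slc7a13, Apoh, Uty and Acsm3. Independent lists of these sizes would share 0.231 higher and 0.557 lower genes. Simulated groups without a difference from WT shared 0, as the adjusted test makes few calls between unchanged groups. Neither value allows for the X and Y transcript pattern that set both genotypes apart from WT. Across genes, which are not independent replicates, the log2 fold changes of ΔPod and K2A correlated at r = 0.879 (Spearman 0.860), and at r = 0.876 without chromosomes X and Y. Because both comparisons use the same WT libraries, simulated unchanged groups correlated at 0.499. The covariance was 0.954, against 0.213 in simulated groups, a difference of 0.741. Both comparisons also share an imbalance, as the length slope was positive in 2 of 3 WT libraries and in 1 of 3 in each genotype. In a simulation that kept the sign of each library's slope, chosen after seeing the data, unchanged groups correlated at 0.729 with a covariance of 0.217 and shared 0 calls. It did not keep the size of the slopes, which among libraries with a negative slope ran from -0.073 in WT 2 to -0.449 in ΔPod 1. The part of the correlation that comes from the full imbalance is thus not known. The 3 WT libraries cannot be split into separate controls of at least 2 for each genotype, so part of the excess in shared calls and in the correlation may come from the shared controls. The difference in sex from WT, which both genotypes share, may also add to it. The number of shared genes was 3, 22 and 5 without WT 1, WT 2 or WT 3, 34 and 205 without ΔPod 2 or ΔPod 3, and 13 and 12 without K2A 1 or K2A 2.

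**Figure D3:**
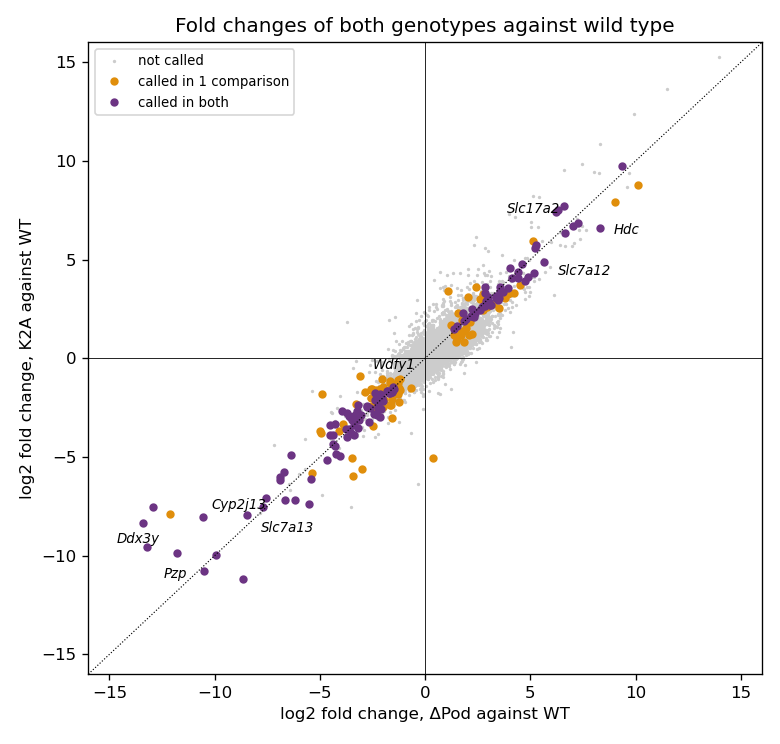
Log2 fold change of every tested gene in ΔPod (horizontal axis) and K2A (vertical axis) against the same 3 WT libraries, with genes called in both in purple, in 1 in orange and in neither in grey, and a dotted line of equality. The 124 genes called in both lie in the upper right (49) or the lower left (75), and r across genes is 0.879 against 0.499 in simulated unchanged groups, or 0.729 where the simulation kept the length classes.

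The comparison of K2A with ΔPod addressed whether a retained but not secreted Ybx1 differs in effect from its absence. No gene passed: edgeR called 0 of 18067 genes, 364 genes had an unadjusted p below 0.05, and DESeq2 called 14. On simulated counts the edgeR test recovered 0% of 2-fold, 4% of 4-fold, 44% of 8-fold and 92% of 32-fold differences here. Groups did not overlap for 5.11% of genes, where chance gives 10%. The genes with the smallest p, which did not pass, were Wdfy1, Gm16867, Lamb3, Wnt7b and Gm45250. Gm16867, a predicted gene, passed with DESeq2 at -5.58 (adjusted p = 1.34e-05) and with the length slope as a covariate at -5.21 (adjusted p = 0.0389). Wdfy1, a phosphoinositide-binding protein gene that differs between mouse substrains, was at 70.2 ± 2.85 CPM in WT, 8.07 ± 0.448 CPM in ΔPod and 38.1 ± 11.1 CPM in K2A (mean ± SD, n = 3 each). It fell in ΔPod (log2 fold change -3.12, SE 0.29, adjusted p = 0.00555) and did not pass in K2A (-0.88, adjusted p = 0.241). Its difference between the genotypes was 2.24 (SE 0.28), which did not pass with edgeR (adjusted p = 0.574) and passed with DESeq2 (adjusted p = 1.43e-09), and its adjusted p ran from 1.43e-09 to 1 over the alternatives. Wnt7b, a Wnt ligand gene of the collecting duct, was at 10.6 ± 3.94, 4.02 ± 1.5 and 19.4 ± 6.2 CPM in WT, ΔPod and K2A, with a difference of 2.27 between the genotypes that did not pass with edgeR (adjusted p from 0.000270 to 1 over the alternatives) and passed with DESeq2 (adjusted p = 0.00409) and with the length slope as a covariate (0.0478).

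Genes called in a single genotype did not pass in the direct comparison either. Spp1 and Atf3, called in ΔPod alone, differed between K2A and ΔPod by -0.66 and -0.97 (adjusted p = 1 each). Slco1a1, Car9 and Slc22a27 differed by 4.24, 0.93 and -0.88, and the K2A calls Fabp1, Npas2, Entpd4 and Lpl by 0.83, -0.96, -0.71 and -0.52, all with adjusted p = 1. Camera called 18 of 43 lists between the genotypes, 12 up and 6 down in K2A, of which 0 held with an estimated correlation and fry called 0. Fatty acid oxidation and PPARA targets were called up (adjusted p = 3.53e-05, with adjusted p = 0.669 with an estimated correlation, and 0.642 without K2A 3). In K2A 3 Cyp4a14, a fatty acid hydroxylase gene that is also on the female-biased list, was at 4782 CPM. It was at 96.9 to 396 CPM in the other mutant libraries and at 3.32 to 7.46 CPM in the WT libraries. Male-biased genes were called up in K2A (adjusted p = 5.56e-06, with adjusted p = 0.366 with an estimated correlation), with a median of 1.29 (0.95 with genes at a count of 0 set to their bound) and no called member (adjusted over the list alone 1 rose). The 9 autosomal members had a median of 0.50. Y-linked counts were absent in ΔPod and summed to only 22, 8 and 0 in K2A 1, K2A 2 and K2A 3. Urothelium markers were called up (adjusted p = 3.53e-05, with adjusted p = 0.669 with an estimated correlation, and 0.330 without ΔPod 3), and ribosomal proteins were called down (adjusted p = 0.000145, with adjusted p = 0.735 with an estimated correlation). The ribosomal median turned from -0.66 to 0.21 without ΔPod 1 and the call was lost without K2A 3 (adjusted p = 0.232). The median and the camera direction differed in sign for the MHC class II, p53, YBX family, female-biased and neuronal lists, none of which was called.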

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

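Chosen only after results were seen were the tests of the podocyte genotype and of transcript length within groups, the fits with a length term or on a single length class, the pooled comparison and the Ybx1 locus test that kept the sex-biased lists. Lamb3, which encodes a laminin chain, stood out because its 3 K2A libraries lay above and its 3 ΔPod libraries below all WT libraries. The difference of K2A from ΔPod was 2.01 on the log2 scale (SE 0.34) and did not pass with edgeR (adjusted p = 1). It passed with DESeq2 (adjusted p = 0.00156) and with the length slope as a covariate (adjusted p = 0.0424), and over all alternatives its adjusted p ran from 0.000238 to 1.

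The first pattern is the set of 124 genes called the same way in both genotypes against WT. Recovery that depends on transcript length is argued against only weakly as its whole cause. With the length slope as a covariate 124 of 124 shared calls stayed called, but that fit raised the shared calls to 1607. Fits on a single length class cannot decide this. The libraries with a positive slope include 1 of ΔPod and 1 of K2A, and the other libraries include 1 of WT. By Xist and Y-linked counts all WT libraries had a male pattern and all mutant libraries a female pattern. This difference in sex is a candidate explanation of the shared calls. Its test used 4 X-linked genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x). Such genes bear on the sex of the animals, for which Xist and the Y-linked counts already gave a pattern. They cannot decide whether the shared calls outside chromosomes X and Y come from a difference in sex. With the length class as a term their median was 0.52 in ΔPod and 0.330 in K2A. These medians lay at percentiles 99.1 and 98.3 of random lists matched on expression but not on length. In that fit, however, Kdm5c was at -0.34 in ΔPod, Ddx3x at -0.05 in K2A and no gene of the 4 passed. Without the length class the medians were 0.345 and 0.252. The podocyte Ybx1 genotype cannot be told apart from the difference in sex, because 0 mutant libraries had the X and Y transcript pattern of the WT libraries. The source of the animals, which the labels give for wild type only, also stays open without a test of its own: of 8 genes that vary between mouse substrains Wdfy1 was called in ΔPod alone and Entpd4 in K2A alone.

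The second pattern is the division of every group by transcript length. Whether length-dependent recovery of RNA is its cause could not be tested: the difference between the libraries of a group correlated with log2 transcript length across genes at r = 0.482 or more in all 3 groups, but the classes were made from the slope on transcript length, so that correlation decides nothing. Different shares of nephron segments in the tissue pieces may contribute, but the test cannot decide this. In it, 4 of 6 segment and glomerulus lists lay outside the range of length-matched random lists on the same side in all 3 groups. These 4 lists were all higher in the same libraries. The random lists were drawn gene by gene, whereas list members vary together (estimated correlation 0.68 for podocyte markers), so their range is too narrow. Both stay open, and no biological explanation from the design was tested, because the division lies within groups.

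The third pattern is the set of called autosomal genes outside the sex-biased lists. Called genes were not in excess around the Ybx1 locus: 1 of 183 lay within 10 Mb of it against 206 of 16975 tested genes (Fisher's exact test, one-sided p = 0.894). With so few genes in the window, the test cannot decide whether DNA carried over around the locus changed single genes there. The gene was Cyp4a12a (log2 fold changes -6.88 and -6.16). With the sex-biased lists kept, Cyp4b1 (-4.99 in ΔPod) was also called there, and 2 of 192 called genes lay in the window against 208 of 16989 tested genes (Fisher's exact test, one-sided p = 0.684). The test covers the region around Ybx1 alone.

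Other splits of the libraries were fitted for each count. For ΔPod against WT 1 of 10 splits, the real 1, reached its 178 genes and the highest other split called 0. For K2A against WT 1 of 10 splits reached 153 and the highest other called 0, and for K2A against ΔPod all 10 splits called 0 with edgeR (in the real split 364 genes had an unadjusted p below 0.05 and DESeq2 called 14). With 10 splits a share below 0.05 cannot be reached. For both genotypes pooled against WT 5 of 84 splits called at least as many genes as the real 370, so chance is not excluded by this count. The other splits called up to 6933 genes (ΔPod 1, K2A 1 and K2A 2 against the rest), and all 4 followed the division by transcript length, which points to a structure of the samples. With the length class as a term the pooled comparison called 968 genes, 440 higher and 528 lower, among them all 370 in the same direction.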

How the results depend on the processing

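The fits with a length term and those on the libraries of a single length class were chosen after seeing the data. Every gene called in ΔPod or K2A against WT that could be tested kept its direction in all 21 alternatives, and the cause of the changes below was not tested except where libraries or genes were left out. Ranges over leaving out a library: genes called in ΔPod against WT 23 to 411, in K2A against WT 3 to 173, in K2A against ΔPod 0 to 2 (Aldh1a3 and Cldn11 without K2A 3) and in both against WT 3 to 205; correlation of fold changes 0.795 to 0.904; lists called between the genotypes 11 to 21; Ybx1 between the genotypes -0.14 to 0.32. With depths near these and 3 libraries per group, 2-fold changes were not recovered in simulated counts.

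With DESeq2, 771 genes were called in ΔPod, 753 in K2A, 467 in both and 14 between the genotypes, the correlation was 0.673 and Ybx1 between the genotypes was at -9.51e-05. Limma-voom with sample weights, which differed up to 141-fold between libraries, called 14246, 14262, 12385 and 5060 genes, with a correlation of 0.921, 6 lists between the genotypes, and Ybx1 at -0.45 in ΔPod (passed), -0.12 in K2A and 0.32 between the genotypes. There Nphs1 turned to -1.47 in ΔPod and -1.35 in K2A and Wt1 to -1.15 and -1.17, and each of these passed. Between the genotypes Igf2 turned to -0.62, Fabp1 to -1.07, fatty acid oxidation and PPARA targets to -0.30, and T, NK and B lymphocyte markers, with a median of -0.23, reversed in test direction. The replicate block gave 270 genes in ΔPod and 232 in K2A, and only the 6 libraries compared gave 54 in ΔPod and 45 in both. Without a filter the correlation was 0.619, and RLE factors put Ybx1 between the genotypes at -0.015. A false discovery rate of 0.05 in 1 genotype with an unadjusted p below 0.05 in the other gave 205 shared genes.

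With the length slope as a covariate 2577 genes were called in ΔPod, 2864 in K2A, 1607 in both and 33 between the genotypes, 11 lists were called between the genotypes, and Ybx1 passed at -0.96 and -0.84. The podocyte list in ΔPod reached 0.47 and turned in direction, with a call (adjusted p = 0.00242), as did in K2A oxidative phosphorylation (-0.25, called, adjusted p = 0.000190) and ribosomal proteins (-0.042, not called). With the class term 715, 739 and 473 genes were called in ΔPod, K2A and both, the correlation was 0.845, and oxidative phosphorylation in K2A was at -0.21 (called, adjusted p = 0.0498), and Ybx1 did not pass at -0.86 and -0.81. The long-class libraries alone gave 4162, 5647, 2651 and 1677 genes (ΔPod, K2A, both, between genotypes) with a correlation of 0.70, where the single ΔPod and K2A libraries are assumed to vary like WT. There Ybx1 was at -0.96 in ΔPod, -1.09 in K2A and -0.12 between the genotypes, Havcr1 turned to -6.06 in ΔPod and -2.52 in K2A, and Nup62cl (1.66), Cbr1 (0.79) and Acsm3 (-1.75) turned between the genotypes. The short-class libraries alone gave 46, 27 and 26 genes (ΔPod, K2A, both) with a correlation of 0.838, where the single WT library is assumed to vary like the others. An estimated correlation left 1, 1 and 0 called lists in ΔPod, K2A and between the genotypes, and fry called 4, 5 and 0.

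Some lists turned in test direction between the genotypes when a library was left out. Their medians ran from -1.08 without K2A 3 to 0.89 without ΔPod 3 for podocyte markers, from -0.33 without K2A 1 to 0.43 without K2A 3 for MHC class II, and from -0.52 without K2A 1 to -0.12 without K2A 3 for T, NK and B lymphocyte markers. They ran from -0.063 without K2A 3 to 1.08 without K2A 2 for fatty acid oxidation and PPARA targets, and from -1.13 without ΔPod 3 to 0.21 without ΔPod 1 for ribosomal proteins. Over all alternatives, 155 values that answer a comparison stayed the same, 71 moved and 6 were stronger. A count stayed the same within a fixed fold of the main count, which took in 181 against 124 shared genes with the replicate block. The correlation stayed the same within its spread over leaving out a library. Ybx1, the named genes and the single lists stayed the same if they kept their direction and their side of the threshold. Of the values of named genes 2874 stayed the same, 135 moved, 331 were weaker, 161 stronger and 11 reversed, and of those of lists 1953 stayed the same, 175 moved, 194 were weaker, 99 stronger and 12 reversed.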

Other observations

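The genes in this part were chosen after their values were seen, and none of these differences between libraries was tested. Some transcripts of the circadian clock stood apart in ΔPod 3 and K2A 3. The clock repressor gene Per1 was at 68.6 and 120 CPM in these libraries and between 4.80 and 25.1 CPM in the other 7, and Dbp, a clock output gene, was at 105 and 183 CPM against at most 25.3 CPM. Ciart was at 3.39 and 14.4 CPM against at most 0.919 CPM, and Arntl, which encodes the activator BMAL1, was at 2.49 CPM in K2A 3 and 8.48 CPM in ΔPod 3, against 6.00 to 26.7 CPM in the other 7. Clock itself (49.9 and 56.7 CPM in ΔPod 3 and K2A 3) and Nr1d2 (87.9 and 107 CPM) lay within the range of the other libraries, as did Nr1d1 in ΔPod 3 (97.2 CPM). The immediate early gene Egr1 was at 165 CPM in ΔPod 3 and 21.9 CPM in K2A 3, against at most 5.05 CPM elsewhere.

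Fat-cell transcripts were high in ΔPod 1, K2A 1 and K2A 2. Ucp1, the uncoupling protein of brown fat, was at 28.2, 20.4 and 109 CPM in these libraries and at most 0.141 CPM in the rest. Adipoq, which encodes adiponectin, was at 15.0, 22.2 and 58.5 CPM and the brown fat gene Cidea at 6.00, 8.12 and 39.4 CPM. The same libraries held the urothelial transcript Upk3a at 15.5, 14.3 and 19.9 CPM. K2A 3 held high levels of transcripts known from fasting: Cyp4a14 was at 4782 CPM, Pdk4 at 260 CPM and the gluconeogenic gene Pck1 at 11520 CPM. Cyp4a14 is also on the female-biased list and was higher in all mutant libraries than in WT. The nuclear RNA Malat1 was at 287 CPM in ΔPod 3 and at 263, 264 and 426 CPM in the K2A libraries, against at most 91.8 CPM in the others, and mt-Co1, a mitochondrially encoded subunit of cytochrome oxidase, was at 32678 CPM in ΔPod 3 and between 23622 and 25676 CPM in K2A, against at most 8292 CPM in the others.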
